A study of Danio rerio with 8 samples.

How the data were processed

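The data are bulk RNA sequencing libraries of zebrafish hearts, made from total RNA extracted with TRIzol from pooled hearts and sequenced on an Illumina HiSeq instrument. The 8 libraries form 4 groups of 2: adult control hearts, adult hearts 3 and 7 days after ablation of ventricular cardiomyocytes, and hearts of larvae 3 days old. The deposited count table holds raw read counts that the authors made by aligning reads to GRCz10 with TopHat2 2.0.13 and counting per gene with HTSeq. The authors' second table holds RPM values, reads scaled to the library total, for the adult libraries, and each of its values matches a count of the first table divided by the total of its library, within a relative tolerance of 1e-04, for 100% of its 23350 genes. Its replicate numbers for control hearts are the reverse of those in the count table, and the numbers of the count table are used here. The annotation release and the strand setting of the counting are not given in the sources used here. The labels name a negative binomial test by the submitters, whose results are not used here.

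Of the 31953 genes in the count table, 23350 took their symbol from the RPM table and 4026 from a table of gene names, and 4577 have none. Counts were analysed in R 4.3.3 with edgeR 4.0.16. All 8 libraries entered 1 fit with a coefficient per group, after filterByExpr, which kept 19330 genes, and TMM scaling. Each comparison is a quasi-likelihood F test on 4 residual degrees of freedom, with p-values adjusted by the Benjamini-Hochberg method and a threshold of 0.05; rose and fell are used of genes past it. The log2 fold changes are those of the edgeR fit, with standard errors back-calculated from the test statistic. CPM are scaled by TMM. The comparisons are 3 dpi, 7 dpi and young against control and 7 dpi against 3 dpi. An exact permutation of 2 against 2 libraries cannot give a p-value under 0.333, so the tests rest on the spread pooled over groups and genes.

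A set of 26 gene lists with 978 genes was fixed before the data were examined, as were the comparisons, the test, the rule for named genes and most alternatives. The lists cover sarcomere, cardiac transcription and stress, cell cycle, ribosomal proteins, ribosome biogenesis, aminoacyl-tRNA synthetases, amino acid transport, amino acid metabolism, mTOR components, integrated stress response, oxidative phosphorylation, fatty acid oxidation, glycolysis, injury response, Wnt targets, epicardium and fibroblasts, immediate early and heat shock genes, macrophages, neutrophils, lymphocytes, adult and embryonic erythroid cells, endothelium and endocardium, smooth muscle and bulbus arteriosus, skeletal muscle, and other organs. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and adjustment over the 26 lists. Since the preset correlation can be too low for genes that move together, the p-value with a correlation estimated from the data is given beside each list that passed. That p-value also rests on the 4 residual degrees of freedom alone, so a call lost there need not come from correlation between genes. Counts adjusted over the list alone repeat the adjustment within the members of that list. Further lists, written after the main results were seen, cover genes of giant and of small proteins, the proteasome, interferon response, circadian clock, hypoxia, cardiac ion channels, mitochondrial ribosome and cholesterol synthesis.

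Genes named in the text come from candidates fixed by rule: per comparison, vmhc, the 8 called genes with the largest rise and the 8 with the largest fall among those with a mean of at least 10 CPM in the higher group, libraries that do not overlap and a symbol that is not a clone name, and from each list the 3 members with the smallest p-value and the member with the highest CPM. Which of these candidates the text names was decided with their values known. Other genes are said to have been chosen after their values were seen. Results of candidates that the text does not name are not reported here. Where a gene has 0 counts in both libraries of a group, the fold is a lower bound computed against a floor of 3 counts over the group, and such folds cover counting error only, since the labels name no molecular identifiers. Genes with 1 to 3 counts in a group are given as levels.

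Overlaps of comparisons count genes called in both, beside the numbers expected from independent calls, and beside 20 simulations in which no group differs and the controls are shared. The controls are 2 libraries and cannot be split between comparisons. The procedure was tested on simulated data with 19330 genes, of which 200 were changed and scored, beside a further set raised 2-fold for lists. It called between 9% and 11% of genes changed 2-fold and between 74% and 82% of genes changed 4-fold, with 3 to 10 false calls among 96 to 109 calls and 0 calls of the wrong sign. Changes of 2-fold were therefore mostly missed in this setting. In the data 3015 to 11643 genes passed, so the adjusted threshold was less strict there, and the share missed was not measured. A gene that is not called is not shown to be unchanged.

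Alternatives tried were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter beyond 1 count, a filter of 10 counts in 4 libraries, only the 2 groups compared, adult libraries only, the replicate number as a block, haemoglobin and mitochondrially encoded genes left out, limma on log2 RPM with a pseudocount of 0.5, a minimum absolute log2 fold change of 1, and each library left out in turn. For lists the rotation test fry was added. Scaling by library totals, a fit without the 7 dpi libraries, and whole reads recovered from the RPM table were chosen after seeing the data. With a library left out, the lone library of its group is assumed to vary like the other groups. Scaling by upper quartiles moved the median log2 fold change by -0.06 at 3 dpi, -0.15 at 7 dpi, and -0.09 in each of the other comparisons. Transcript lengths and raw reads were not analysed here, so length bias was examined through lists of genes of giant and small proteins. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.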

Results

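Bulk RNA sequencing measured gene expression in zebrafish hearts. The 8 libraries fall into 4 groups of 2: control adult hearts, adult hearts 3 and 7 days post injury (dpi), and hearts of larvae 3 days old, called young here. Each adult library pooled 4 to 6 hearts and each young library about 500. The injury was an ablation of ventricular cardiomyocytes that carry a bacterial nitroreductase under the promoter of vmhc, a ventricular myosin gene; metronidazole, given at 5 mM for 48 hours, is turned into a toxin by that enzyme. Control adults correspond to 0 dpi with 0.1% dimethyl sulfoxide, the vehicle. No group received metronidazole without ablation, so effects of the drug and of the ablation cannot be told apart in the adult comparisons with control. The series title names amino acids and mTOR signalling in heart regeneration, so lists of these genes were among those fixed before the data were examined. Total counts were 10868019 and 17734354 in the control libraries, 11856744 and 14190080 at 3 dpi, 26204332 and 26628897 at 7 dpi, and 17266995 and 19457858 in young hearts. The labels do not say that replicate pools came from separate clutches or experiments, so every p-value measures the spread between these pools.

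The libraries grouped by condition. The leading component of log2 CPM (counts scaled to the size of the library) held 62.8% of the variance and separated young from adult hearts, and the next held 24.0% and separated 7 dpi from the other adult libraries. Mitochondrially encoded transcripts took 14.9% and 15.3% of counts in control hearts, 7.14% and 9.54% at 3 dpi, 24.7% and 28.2% at 7 dpi, and 7.59% and 7.70% in young hearts. The 7 dpi libraries detected 18744 and 17785 genes, fewer than the 20660 to 23312 of the other 6 libraries, although they were the deepest. Genes of small proteins and genes of giant proteins, as lists chosen after the main results were seen, also set the 7 dpi libraries apart. The median log2 CPM of the small list minus that of the giant list was -1.39 and -0.30 in control, -0.59 and -0.82 at 3 dpi, 2.28 and 1.98 at 7 dpi, and 0.14 and 0.05 in young hearts. Names of the deposited columns carry 3 run prefixes. Control and 3 dpi share 1 of them, whereas 7 dpi and young each have their own, so run and group cannot be told apart in any comparison with 7 dpi or young; the labels state that the libraries were sequenced together.

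**Figure D1:**
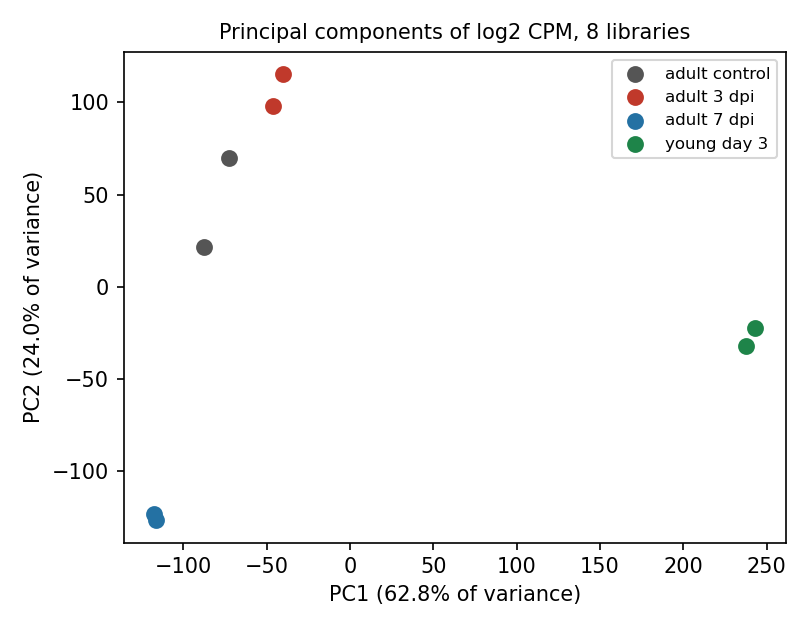
Each point is 1 of the 8 libraries, placed by its scores on the leading components of TMM-scaled log2 CPM (no unit), with the percentage of variance on each axis. Young libraries lie apart along PC1 (62.8%) and 7 dpi libraries along PC2 (24.0%).

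**Figure D2:**
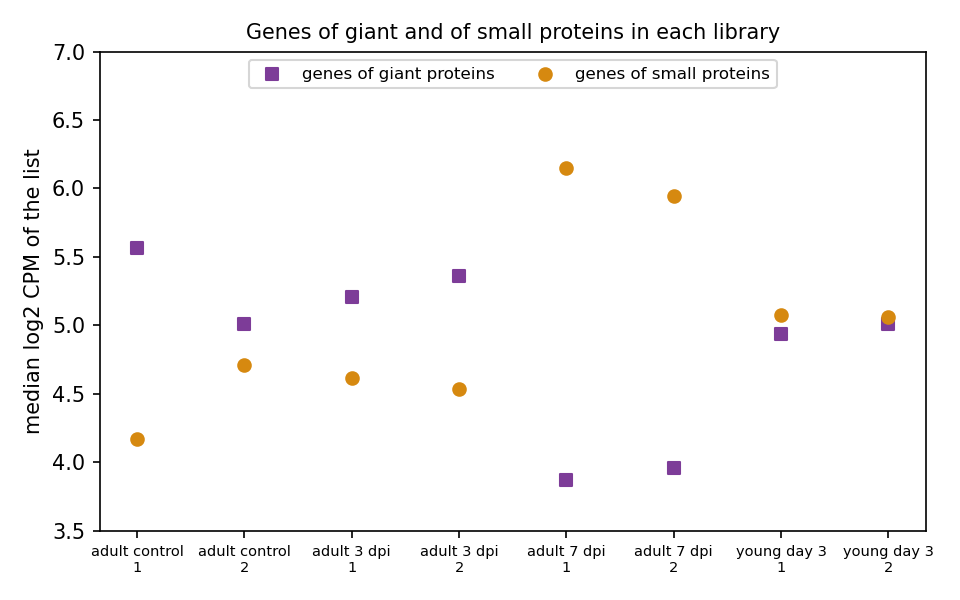
Median log2 CPM of 110 genes of giant proteins (squares) and 140 genes of small proteins (circles) in each of the 8 libraries. The small list exceeds the giant list by 2.28 and 1.98 in the 7 dpi libraries and lies below it by up to 1.39 in the other adult libraries.

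Wound signals and macrophage genes were higher at 3 dpi than in control hearts, and genes of oxidative metabolism were lower; this comparison addresses the early response to ablation. The interleukin 11 gene il11a (ENSDARG00000037859), which encodes a cytokine, stood at 1.23 and 0.236 CPM in control and at 268 and 130 CPM at 3 dpi, a log2 fold change of 8.20 (SE 0.59, n = 2 libraries per group, adjusted p = 7.60e-05, edgeR quasi-likelihood). Its paralog il11b (ENSDARG00000058557) rose by 5.95 (SE 0.46). nppb (ENSDARG00000052958), a natriuretic peptide gene known as a marker of cardiac stress, rose by 2.68 (SE 0.28), and ankrd1a (ENSDARG00000075263), which encodes a stress-responsive muscle ankyrin repeat protein, by 8.69 (SE 0.65). Of 19330 genes tested, 3015 passed, 1749 higher and 1266 lower at 3 dpi. The groups did not overlap in 56.7% of genes, where chance gives 33.3%. Without control replicate 2 the count was 1050, without 3 dpi replicate 1 it was 985, and with only these 2 groups in the fit 1823. Scaling by library totals moved the median log2 fold change by 0.44 and raised the share of called genes that rose from 58.0% to 86.8%.

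Injury genes and markers of several other cell types moved at 3 dpi. In the injury response list 23 of 44 tested genes rose and 1 fell (26 and 1 adjusted over the list alone), with a median log2 fold change of 1.301 (camera adjusted p = 1.81e-09, and adjusted p = 0.371 with an estimated correlation). Of 32 macrophage markers 25 rose and 0 fell, also when adjusted over the list alone, with a median of 1.71 (camera adjusted p = 1.94e-08, and adjusted p = 0.424 with an estimated correlation). havcr1 rose by 2.93 (SE 0.30) and grn1, a progranulin gene, by 5.04 (SE 0.59). Among 25 neutrophil markers 11 rose and 2 fell (13 and 3 adjusted over the list alone), median 1.14 (camera adjusted p = 0.00256, and adjusted p = 0.424 with an estimated correlation). mmp9, a matrix protease, rose by 2.84 (SE 0.36), whereas lyz, lysozyme, changed by -2.21 (SE 0.42). Before scaling, counts summed over the libraries of a group went from 3262 in control to 1727 at 3 dpi for npsn. For mpx they went from 869 to 1021. The neutrophil list shares mmp9, mmp13a, il1b and cxcr4b with the injury list, so these lists are not independent. Lymphocyte markers had a median of -0.63, with 0 of 23 higher and 1 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.00868, and adjusted p = 0.371 with an estimated correlation), and the list no longer passed without 3 dpi replicate 2 (camera adjusted p = 0.0587). In the list of smooth muscle and bulbus arteriosus 12 of 20 genes rose and 1 fell, the same counts adjusted over the list alone, median 1.63 (camera adjusted p = 4.39e-06, and adjusted p = 0.371 with an estimated correlation). Its contractile genes cnn1b and tagln rose by 4.95 (SE 0.41) and 2.77 (SE 0.34). Epicardium and fibroblast genes had a median of 0.43, with 9 of 39 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.0132, and adjusted p = 0.424 with an estimated correlation), a call lost without control replicate 1 (camera adjusted p = 0.0965). aldh1a2, of retinoic acid synthesis, rose by 1.73 (SE 0.23) and loxa, of collagen crosslinking, by 3.70 (SE 0.54).

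Endothelial and endocardial markers did not shift as a list: 4 of 35 rose and 6 fell (6 and 8 adjusted over the list alone), with a median of -0.15, a mean of 0.0005 and a median of 0.25 under library totals (camera adjusted p = 0.499). sele, which encodes the endothelial adhesion molecule E-selectin, rose by 2.51 (SE 0.30). Of 22 adult erythroid genes 1 rose and 5 fell (1 and 13 adjusted over the list alone), median -0.98 (camera adjusted p = 0.00145, and adjusted p = 0.371 with an estimated correlation). The remaining lists of cell types did not pass, although under library totals embryonic erythroid genes (camera adjusted p = 0.00855), skeletal muscle (0.00230) and other organs (0.0190) did, in the direction of down. In these lists 4, 2 and 8 members had 0 counts in both groups. Such genes cannot follow the shift that library totals bring. Embryonic erythroid genes had a median of -0.69, or 0 with unseen genes at their bound (0 of 10 higher, 1 lower, with camera adjusted p = 0.165), and markers of other organs a median of 0 and a mean of 0.14 with a test direction of down (2 of 42 higher, 4 lower, with camera adjusted p = 0.554). Skeletal muscle genes had a median of -0.60, or -0.28 at the bound (1 of 31 higher, 5 lower, with camera adjusted p = 0.120), and passed without control replicate 1 (camera adjusted p = 0.0173).

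Transcripts of oxidative phosphorylation and fatty acid oxidation were lower at 3 dpi, in libraries whose mitochondrially encoded share was 7.14% and 9.54% against 14.9% and 15.3%. Of 88 nuclear genes of oxidative phosphorylation, 61 fell and 1 rose (83 and 2 adjusted over the list alone), with a median of -1.15, or -0.70 under library totals with 29 lower and 2 higher (camera adjusted p = 1.95e-20, and adjusted p = 0.424 with an estimated correlation). cox7a1, the heart and muscle form of a cytochrome oxidase subunit, changed by -2.66 (SE 0.45), and cox6a1 was the gene that rose, by 1.57 (SE 0.26). In fatty acid oxidation 23 of 35 genes fell and 0 rose (26 and 0 adjusted over the list alone), median -1.40 (camera adjusted p = 4.29e-12, and adjusted p = 0.390 with an estimated correlation). fabp3, a fatty acid binding protein of muscle, changed by -2.16 (SE 0.38), decr1 by -2.30 (SE 0.30), and pdk2a, a kinase that restrains pyruvate dehydrogenase, by -2.31 (SE 0.23). Glycolysis genes were mixed, with 6 of 39 higher and 13 lower (7 and 17 adjusted over the list alone) and a median of -0.58, or -0.16 under library totals with 10 higher and 9 lower (camera adjusted p = 0.00709, and adjusted p = 0.371 with an estimated correlation): hk2, a hexokinase gene, rose by 3.12 (SE 0.42) and gapdh changed by -2.65 (SE 0.52). The mitochondrial ADP/ATP carrier gene slc25a4 changed by -5.06 (SE 0.38).

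Sarcomere genes had a median of -0.86, or -0.43 under library totals with 7 higher and 2 lower there. In the main fit 5 of 37 were higher and 3 lower (5 and 12 adjusted over the list alone, with camera adjusted p = 0.0172, and adjusted p = 0.625 with an estimated correlation). That call was lost without control replicate 1 (camera adjusted p = 0.0782) and without 3 dpi replicate 1 (camera adjusted p = 0.449). cmlc1, a cardiac myosin light chain gene, changed by -1.51 (SE 0.49, edgeR adjusted p = 0.0617), and passed without control replicate 1 (adjusted p = 0.0421) or 3 dpi replicate 2 (adjusted p = 0.0230), with upper-quartile scaling (adjusted p = 0.0462), with DESeq2 (adjusted p = 0.000367), with no filter (adjusted p = 0.00866) and with the filter of 10 counts (adjusted p = 0.0411). vmhc (ENSDARG00000079564) rose from 202 and 220 CPM in control to 1051 and 546 CPM at 3 dpi, by 1.92 (SE 0.33). Its paralog vmhcl, named after its values were seen, stood at 20630 and 20970 CPM in control and 4346 and 7380 CPM at 3 dpi; how reads shared by such paralogs were assigned is not given in the sources used here. In the list of cardiac transcription and stress genes 2 of 19 rose and 1 fell (2 and 4 adjusted over the list alone), with a median of -0.16, a mean of 0.23 and a median of 0.24 under library totals (camera adjusted p = 0.880).

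Aminoacyl-tRNA synthetases and genes of ribosome biogenesis and the cell cycle were higher as lists at 3 dpi, and ribosomal protein genes were lower. Among aminoacyl-tRNA synthetases 14 of 21 rose and 0 fell (19 and 0 adjusted over the list alone), median 0.94 (camera adjusted p = 1.79e-07, and adjusted p = 0.424 with an estimated correlation), with yars at 1.67 (SE 0.21) and sars at 1.52 (SE 0.20). In ribosome biogenesis 18 of 47 genes rose and 1 fell (26 and 2 adjusted over the list alone), median 0.58 (camera adjusted p = 4.74e-07, and adjusted p = 0.424 with an estimated correlation). npm1a, nucleophosmin, rose by 1.60 (SE 0.23). Ribosomal protein genes had a median of -0.53, or -0.07 under library totals, with 0 of 82 higher and 1 lower (0 and 0 adjusted over the list alone; camera adjusted p = 3.05e-07, and adjusted p = 0.597 with an estimated correlation), a list call lost without control replicate 2 (camera adjusted p = 0.102). All 53 cell cycle genes had fold changes above 0, of which 10 passed (20 adjusted over the list alone), median 1.5025 (camera adjusted p = 1.79e-07, and adjusted p = 0.498 with an estimated correlation). anln, anillin of the cytokinetic ring, rose by 2.30 (SE 0.41). With the rotation test fry, lists that no longer passed at 3 dpi were cell cycle (adjusted p = 0.147), ribosomal proteins (0.231), sarcomere (0.338), oxidative phosphorylation (0.0650) and neutrophils (0.0912).

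Single amino acid and mTOR genes changed at 3 dpi, while their lists did not pass. In amino acid transport 8 of 35 genes rose and 4 fell (9 and 7 adjusted over the list alone), median 0.33 (camera adjusted p = 0.432). slc43a2b (ENSDARG00000061120), a transporter gene of large neutral amino acids, rose from 2.38 and 3.19 CPM to 163 and 88.0 CPM (5.48, SE 0.41). slc7a7, of cationic amino acid exchange, rose by 3.51 (SE 0.34), and slc43a1b changed by -2.15 (SE 0.28). Amino acid metabolism had 6 of 46 genes higher and 10 lower (11 and 13 adjusted over the list alone), a median of 0.07 and a mean of 0.17 with a test direction of down, or a median of 0.52 under library totals with 15 higher and 5 lower (camera adjusted p = 0.969). odc1, the rate-limiting enzyme of polyamine synthesis, rose by 2.36 (SE 0.21), and gfpt2, of hexosamine synthesis, by 4.72 (SE 0.43). Of 50 mTOR pathway genes 4 rose and 8 fell (5 and 10 adjusted over the list alone), median -0.23, or 0.23 under library totals (camera adjusted p = 0.165). eif4e1c (ENSDARG00000012274), of the eIF4E family of cap-binding translation factors, rose from 10.8 and 9.80 CPM to 51.6 and 62.0 CPM (2.46, SE 0.21). sesn1 and akt1s1, both known as inhibitors of mTOR complex 1, changed by -1.60 (SE 0.28) and -1.32 (SE 0.24), the latter not past the threshold with limma on log2 RPM (-0.84). Integrated stress response genes had a median of 0.35 (4 of 24 higher, 2 lower; 5 and 2 adjusted over the list alone, with camera adjusted p = 0.208), and hspa5, an endoplasmic reticulum chaperone, rose by 1.64 (SE 0.25). Wnt target genes had a median of 0.05 (1 of 22 higher, 0 lower, with camera adjusted p = 0.823). Immediate early and heat shock genes had a median of 0.45 (7 of 30 higher, 3 lower, with camera adjusted p = 0.0915) and passed without 3 dpi replicate 2 (camera adjusted p = 0.0157) and with fry (adjusted p = 0.0446).

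**Figure D3:**
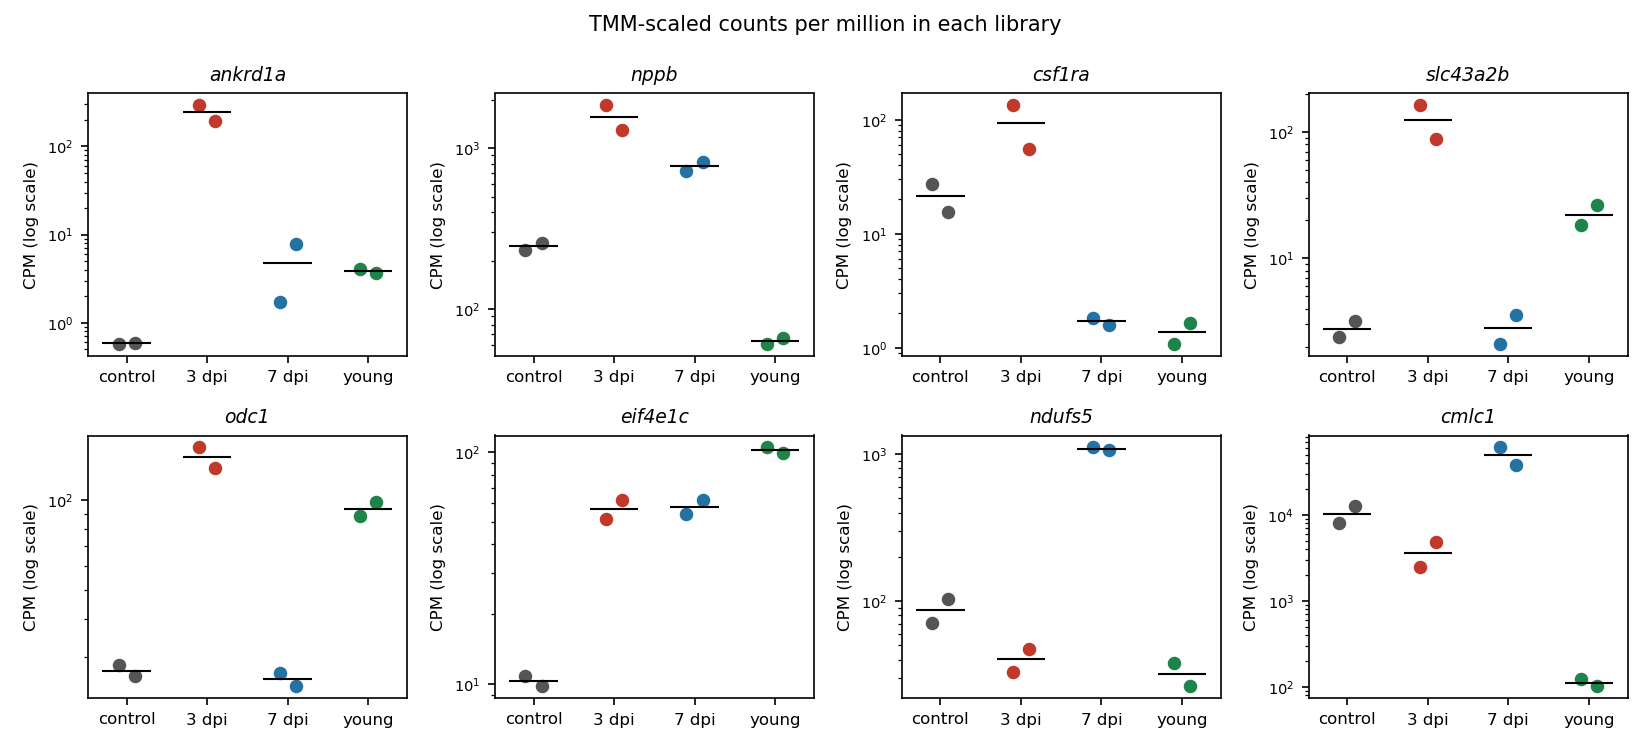
TMM-scaled CPM on a log axis for 8 genes in the 2 libraries of each group; points are libraries and lines group means. slc43a2b stands at 163 and 88.0 CPM at 3 dpi and at 2.102 and 3.57 CPM at 7 dpi, and eif4e1c at 51.6 and 62.0 CPM and at 54.0 and 62.4 CPM.

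At 7 dpi genes of ribosomal proteins and of oxidative phosphorylation were higher than in control hearts, and amino acid transporters and neutrophil markers were lower; this comparison addresses a later time after ablation. rps28 (ENSDARG00000035860), a ribosomal protein gene, stood at 255 and 419 CPM in control and 5044 and 3800 CPM at 7 dpi, a log2 fold change of 3.71 (SE 0.36, n = 2 libraries per group, adjusted p = 0.000178, edgeR quasi-likelihood). ndufs5 (ENSDARG00000006290), of respiratory complex I, rose by 3.64 (SE 0.32), and tagln (ENSDARG00000045408), the smooth muscle gene transgelin, by 4.37 (SE 0.36). In the same libraries genes of small proteins rose and genes of giant proteins fell: 113 of 140 small rose (median 1.61, quartiles 0.86 to 2.04) and 80 of 110 giant fell (median -1.08, quartiles -1.85 to -0.71). Over all genes 7486 of 19330 passed, 3616 higher and 3870 lower, and groups did not overlap in 68.3% of genes against 33.3% by chance. Without control replicate 1 the count was 4093. Library totals moved the median by -1.24, called 11770 genes and lowered the share that rose from 48.3% to 6.19%.

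Of 82 ribosomal protein genes 80 rose and 1 fell at 7 dpi (81 and 1 adjusted over the list alone), median 2.17, or 0.93 under library totals (camera adjusted p = 3.10e-28, and adjusted p = 0.571 with an estimated correlation). rps15a rose by 3.502 (SE 0.36) and rps2 by 1.93 (SE 0.35). In oxidative phosphorylation 78 of 88 genes rose and 0 fell (81 and 0 adjusted over the list alone), median 1.81, or 0.57 under library totals (camera adjusted p = 1.21e-22, and adjusted p = 0.571 with an estimated correlation), and cox7a2a rose by 3.22 (SE 0.25). Both medians stand beside the 1.61 of genes of small proteins, or 0.37 under library totals, and beside mitochondrially encoded shares of 24.7% and 28.2%. Glycolysis genes had a median of 0.72, but -0.55 and no list call under library totals, where 0 genes were higher and 15 lower, with 19 of 39 higher and 5 lower (22 and 5 adjusted over the list alone; camera adjusted p = 0.00486, and adjusted p = 0.571 with an estimated correlation). Fatty acid oxidation did not pass (15 of 35 higher, 6 lower; median 0.69, or -0.57 under library totals, with camera adjusted p = 0.0942) except without 7 dpi replicate 2 (camera adjusted p = 0.0339). fabp3 rose by 1.81 (SE 0.37) and pdk2a changed by -2.06 (SE 0.23). Sarcomere genes went both ways. Of 37, 13 rose and 8 fell, with a median of 0.52, or -0.74 under library totals (camera adjusted p = 0.0628). The list passed without control replicate 1, without either 3 dpi library or without 7 dpi replicate 2 (camera adjusted p from 0.0211 to 0.0463), and under library totals in the direction of up, relative to a median of all genes of -1.37 there and with 5 higher and 17 lower (camera adjusted p = 0.0164). actc1a, cardiac actin, rose by 3.57 (SE 0.39), smyd1b by 3.35 (SE 0.43) and cmlc1 by 2.27 (SE 0.50). ttn.1, of the giant protein titin, and myom1b, myomesin, named after their values were seen, changed by -4.53 (SE 0.69) and -2.60 (SE 0.43). vmhc rose by 1.89 (SE 0.33) and nppb by 1.66 (SE 0.27). The rises of vmhc, nppb and fabp3 did not pass under library totals, with log2 fold changes of 0.65, 0.41 and 0.58.

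In amino acid transport 17 of 35 genes fell at 7 dpi and 0 rose (18 and 0 adjusted over the list alone), median -1.15, or -1.14 with unseen genes at their bound (camera adjusted p = 0.000841, and adjusted p = 0.571 with an estimated correlation). Genes of giant proteins had a similar median of -1.08, with quartiles of -1.85 and -0.71. Under library totals the medians were -2.40 for transporters and -2.36 for giant proteins. Whether transcript size bears on the transporters was not tested. slc38a9 (ENSDARG00000032769), known as a lysosomal amino acid sensor upstream of mTOR complex 1, changed by -3.16 (SE 0.35), and slc6a9, a glycine transporter gene, by -2.27 (SE 0.35). Amino acid metabolism had 10 of 46 genes higher and 8 lower, a median of 0.14, a mean of -0.09, and a median of -1.11 under library totals with 2 higher and 31 lower, and -0.01 under upper-quartile scaling (camera adjusted p = 0.470). glsb, a glutaminase gene, changed by -2.11 (SE 0.26) and psph, of serine synthesis, rose by 1.97 (SE 0.28), a call lost with limma on log2 RPM (0.725). Of 50 mTOR pathway genes 15 rose and 12 fell, the same adjusted over the list alone, median 0.05, or -1.20 under library totals with 2 higher and 31 lower, and -0.10 under upper-quartile scaling (camera adjusted p = 0.470). eif4e1c rose by 2.498 (SE 0.22), deptor, an inhibitor of mTOR, changed by -2.19 (SE 0.29), and rps6, a ribosomal protein phosphorylated downstream of mTOR, rose by 1.65 (SE 0.33). Under library totals rps6 had 0.41 and did not pass. Aminoacyl-tRNA synthetases had 11 of 21 higher and 1 lower (median 0.65; camera adjusted p = 0.00343, and adjusted p = 0.679 with an estimated correlation), but a median of -0.59 under library totals, where the call was lost. Ribosome biogenesis had 22 of 47 higher and 3 lower (median 0.57; camera adjusted p = 0.000462, and adjusted p = 0.671 with an estimated correlation), but a median of -0.69 under library totals, where the call was lost. Integrated stress genes had 12 of 24 higher and 3 lower (median 0.90; camera adjusted p = 0.00766, and adjusted p = 0.571 with an estimated correlation), but a median of -0.36 under library totals, where the call was lost. ddit3, which encodes the stress factor CHOP, changed by -5.37 (SE 0.53).

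Markers of other cell types at 7 dpi went both ways. Of 25 neutrophil markers 15 fell and 0 rose (17 and 0 adjusted over the list alone), median -1.80, or -1.69 with unseen genes at their bound (camera adjusted p = 0.000752, and adjusted p = 0.571 with an estimated correlation). Genes of giant proteins had a median of -1.08 in the same comparison. mpx, myeloperoxidase, changed by -4.27 (SE 0.63) and npsn by -3.22 (SE 0.44). Macrophage markers had 4 of 32 higher and 8 lower, median -0.36, or -1.62 under library totals with 2 higher and 20 lower (camera adjusted p = 0.528): csf1ra, a receptor of macrophage growth factors, changed by -3.65 (SE 0.50) and apoeb, an apolipoprotein E gene, rose by 5.51 (SE 0.75). In smooth muscle and bulbus 12 of 20 genes rose and 3 fell (12 and 4 adjusted over the list alone), median 1.44, or 0.23 under library totals with 6 higher and 6 lower (camera adjusted p = 0.0202, and adjusted p = 0.571 with an estimated correlation), a call lost without control replicate 2 (camera adjusted p = 0.0888). acta2, smooth muscle actin, rose by 4.04 (SE 0.37). Skeletal muscle genes had 14 of 31 higher and 0 lower, median 1.28, or 1.21 at the bound and 0.12 under library totals, with 9 higher and 4 lower (camera adjusted p = 0.00141, and adjusted p = 0.571 with an estimated correlation). Lymphocyte markers did not pass (2 of 23 higher, 9 lower, median -1.28, camera adjusted p = 0.0641) but did without either 3 dpi library or 7 dpi replicate 2 (camera adjusted p from 0.0314 to 0.0468) and with fry (adjusted p = 0.0105). Endothelial and endocardial markers had 6 of 35 higher and 10 lower, median -0.27, or -1.53 under library totals with 0 higher and 28 lower (camera adjusted p = 0.528, and fry adjusted p = 0.0105). kdr, a receptor of vascular endothelial growth factor, changed by -2.85 (SE 0.34) and notch1b by -1.89 (SE 0.31). Markers of other organs did not pass as a list (7 of 42 higher, 1 lower, median 0, camera adjusted p = 0.343) but did under library totals in the direction of up, relative to all genes, with a median of -0.48, 3 higher and 5 lower (camera adjusted p = 4.05e-06). Of these markers 11 had 0 counts in both groups and 7 in 1 group. Genes at 0 in both cannot follow the shift that library totals bring, so that call is no evidence of a rise. Of single genes, epcam, of epithelial adhesion, stood at 33.2 and 28.8 CPM at 7 dpi against 0.0820 and 0 CPM in control, krt5 at 1357 and 63.5 CPM against 0.901 and 10.4 CPM, and ctrb1, a pancreatic chymotrypsinogen gene, rose by 5.53 (SE 0.80). The call of krt5 was lost without control replicate 1 (edgeR adjusted p = 0.0588).

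Between 3 and 7 dpi injury genes, markers of macrophages and neutrophils and cell cycle genes fell, and genes of oxidative phosphorylation rose; this comparison tests the change between the times directly. ankrd1a changed by -5.64 (SE 0.53, n = 2 libraries per group, adjusted p = 4.36e-05, edgeR quasi-likelihood), to 1.74 and 7.89 CPM at 7 dpi. il11a went from 268 and 130 CPM at 3 dpi to 0 and 0.0830 CPM at 7 dpi. Of 19330 genes tested 9843 passed, 4410 higher and 5433 lower at 7 dpi, with groups that did not overlap in 73.1% of genes against 33.3% by chance. Genes of small proteins rose here too (106 of 140, median 1.57, but -0.11 under library totals, 8 fell) and those of giant proteins fell (71 of 110, median -1.35, or -2.94 under library totals). Library totals moved the median by -1.69, and 6.20% of called genes rose in place of 44.8%.

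In the injury list 32 of 44 genes fell from 3 to 7 dpi and 1 rose, the same adjusted over the list alone, median -1.87 (camera adjusted p = 2.42e-05, and adjusted p = 0.586 with an estimated correlation). Outside that list, fosl1a, an AP-1 transcription factor gene of the immediate early list, changed by -4.67 (SE 0.34). The intercalated disc gene xirp1, of the sarcomere list, changed by -3.50 (SE 0.32). Of 32 macrophage markers 26 fell and 0 rose, also adjusted over the list alone, median -2.101, or -1.99 at the bound (camera adjusted p = 3.84e-05, and adjusted p = 0.627 with an estimated correlation). csf1ra changed by -5.79 (SE 0.52), spi1b, a myeloid transcription factor gene, by -3.94 (SE 0.37) and havcr1 by -3.33 (SE 0.31). Neutrophil markers had 21 of 25 lower and 0 higher (22 and 0 adjusted over the list alone), median -3.27, or -2.92 at the bound (camera adjusted p = 2.42e-05, and adjusted p = 0.586 with an estimated correlation), with mmp9 at -4.64 (SE 0.42). Lymphocyte markers did not pass (5 of 23 higher, 6 lower, median -1.16, camera adjusted p = 0.645). In the cell cycle list 38 of 53 fell and 1 rose (39 and 1 adjusted over the list alone), median -2.17 (camera adjusted p = 0.000309, and adjusted p = 0.654 with an estimated correlation), and anln changed by -4.29 (SE 0.47). With the rotation test fry the cell cycle and sarcomere lists did not pass (adjusted p = 0.0687 and 0.0659). Among smooth muscle genes, which did not pass as a list (median -0.54, or -0.40 at the bound, with camera adjusted p = 0.568), cnn1b changed by -3.04 (SE 0.37) and acta2 rose by 2.18 (SE 0.34).

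Oxidative phosphorylation genes rose from 3 to 7 dpi in 86 of 88 cases and fell in 0 (87 and 0 adjusted over the list alone), median 2.97, or 1.28 under library totals (camera adjusted p = 6.24e-29, and adjusted p = 0.586 with an estimated correlation), beside a median of 1.57 for genes of small proteins, or -0.11 under library totals. Of 82 ribosomal protein genes 81 rose, median 2.64, or 0.94 under library totals (camera adjusted p = 8.62e-28, and adjusted p = 0.586 with an estimated correlation). Fatty acid oxidation had 24 of 35 higher and 1 lower, the same adjusted over the list alone, median 1.85, or 0.15 under library totals with 15 higher and 11 lower (camera adjusted p = 2.68e-07, and adjusted p = 0.586 with an estimated correlation). decr1 rose by 3.61 (SE 0.32) and fabp3 by 3.97 (SE 0.41). Glycolysis had 22 of 39 higher and 6 lower, median 0.94, but -0.77 under library totals with 5 higher and 21 lower (camera adjusted p = 0.000242, and adjusted p = 0.586 with an estimated correlation), with gapdh at 3.99 (SE 0.55). Sarcomere genes had 21 of 37 higher and 8 lower, median 1.08, but -0.63 under library totals with 8 higher and 17 lower (camera adjusted p = 0.00507, and adjusted p = 0.654 with an estimated correlation). Skeletal muscle genes had 14 of 31 higher and 2 lower, median 2.76, or 1.55 at the bound (camera adjusted p = 0.00117, and adjusted p = 0.586 with an estimated correlation). vmhc did not differ beyond its error (-0.03, SE 0.32, edgeR adjusted p = 0.968), and its sign turned without 3 dpi replicate 1 (0.51) and without 7 dpi replicate 1 (0.10). Library totals (-1.73, adjusted p = 0.00118) and limma on log2 RPM (-1.65, adjusted p = 0.00469) called it lower at 7 dpi.

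Amino acid transporters fell from 3 to 7 dpi in 20 of 35 cases and rose in 5 (21 and 5 adjusted over the list alone), median -1.92, or -1.89 at the bound (camera adjusted p = 0.00259, and adjusted p = 0.586 with an estimated correlation). Genes of giant proteins had a median of -1.35 in the same comparison. slc43a2b changed by -5.46 (SE 0.41), to 2.102 and 3.57 CPM, and slc7a7 by -4.20 (SE 0.36). odc1 changed by -2.46 (SE 0.21) and asns, asparagine synthetase, by -2.23 (SE 0.27). Of 50 mTOR pathway genes 18 rose and 11 fell, median 0.12, or -1.57 under library totals with 2 higher and 39 lower (camera adjusted p = 0.223, and fry adjusted p = 0.0481). Genes of the translation repressors 4E-BP rose, eif4ebp1 by 2.13 (SE 0.23) and eif4ebp3 by 3.78 (SE 0.35), and akt1s1 rose by 2.30 (SE 0.24). eif4ebp1 did not pass under library totals (0.44), nor did acta2 (0.49), and akt1s1 did not pass with limma on log2 RPM (0.60). eif4e1c stood at 51.6 and 62.0 CPM at 3 dpi and at 54.0 and 62.4 CPM at 7 dpi. Lists that passed under other settings alone were integrated stress (without 3 dpi replicate 1, camera adjusted p = 0.0499), epicardium and fibroblast (without 3 dpi replicate 2, camera adjusted p = 0.0338, and fry, adjusted p = 0.0286) and adult erythroid genes (without either control library or 7 dpi replicate 1, camera adjusted p from 0.0078 to 0.0441, the replicate block, 0.0333, fry, 0.0336, and library totals, 0.00275). Among others, fry passed lymphocyte (0.0418), endothelial (0.0275) and embryonic erythroid lists (0.0275), and library totals aminoacyl-tRNA synthetases (0.00816, down), embryonic erythroid genes (3.60e-05) and other organs (5.62e-07). In the embryonic erythroid and other organ lists 6 and 9 members had 0 counts in both groups. Such genes cannot follow the shift that library totals bring.

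**Figure D4:**
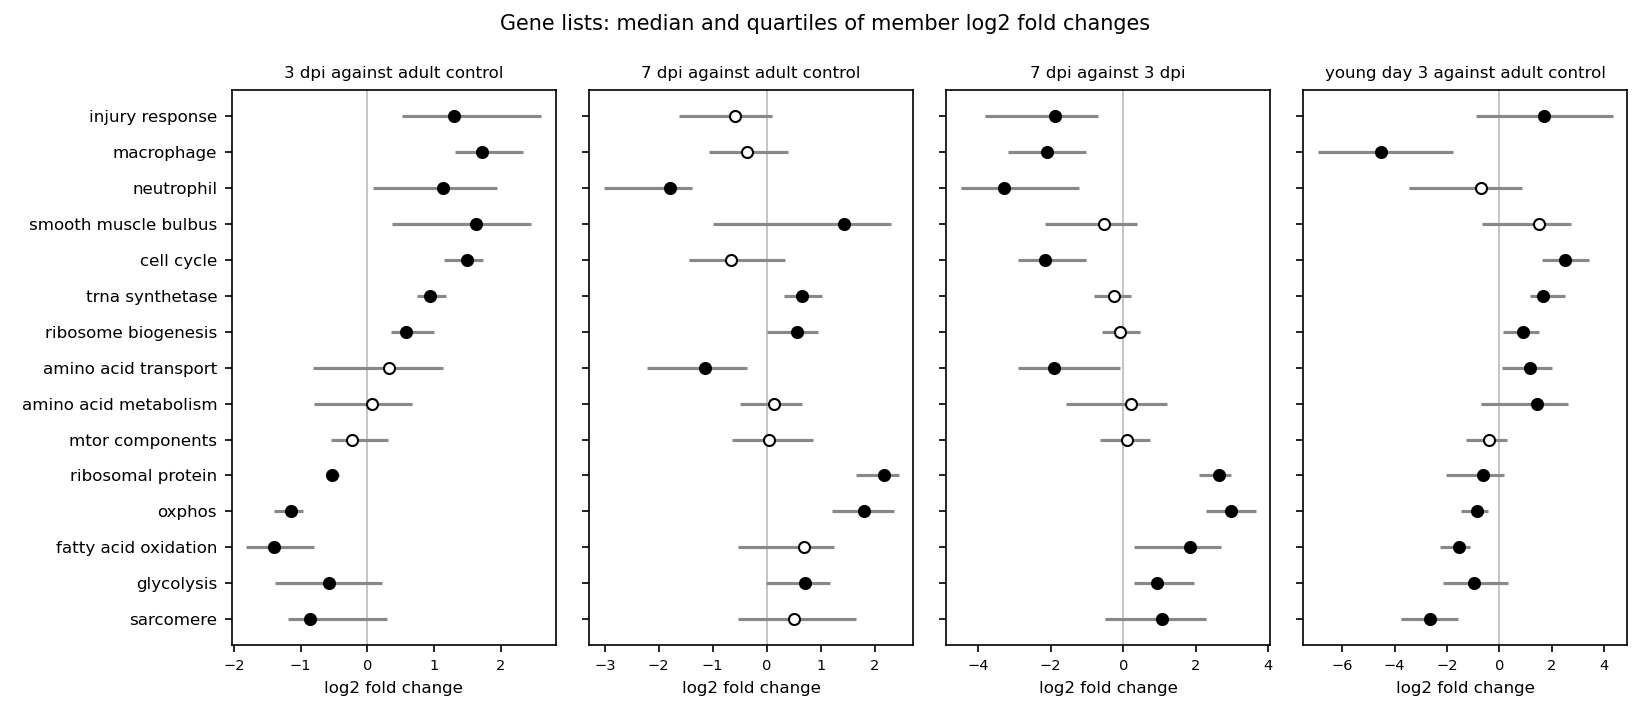
Median (point) and quartiles (line) of the log2 fold changes of the genes of 15 lists in each of the 4 comparisons; filled points passed camera with its preset correlation, and 0 lists passed with an estimated one. Oxidative phosphorylation stands at -1.15 at 3 dpi and 1.81 at 7 dpi against control (-0.70 and 0.57 under library totals). Under library totals the sign of other lists turns as well, and the text gives some of these.

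Levels of cell cycle genes, amino acid transporters and genes of amino acid metabolism were higher in the libraries of young hearts than in adult control. Levels of sarcomere genes, markers of macrophages and lymphocytes and genes of fatty acid oxidation were lower. This comparison sets pools of larval hearts against adult hearts. slc1a4 (ENSDARG00000000551), a transporter gene of neutral amino acids, stood at 1.23 and 1.00 CPM in control and 195 and 201 CPM in young hearts, a log2 fold change of 7.48 (SE 0.41, n = 2 libraries per group, adjusted p = 6.27e-07, edgeR quasi-likelihood). psat1 (ENSDARG00000016733), of serine synthesis, rose by 5.61 (SE 0.26), and cmlc1 (ENSDARG00000032976) went from 7977 and 12720 CPM to 122 and 102 CPM (-6.53, SE 0.61). Of 19330 genes tested 11643 passed, 6304 higher and 5339 lower in young hearts, with groups that did not overlap in 83.7% of genes against 33.3% by chance. Markers of skeletal muscle and of other organs were also far higher in the young libraries, as given with the cell types. Whether RNA of other larval organs contributes to any difference between young and control given here was not tested. Library totals moved the median by 0.61 and raised the share of called genes that rose from 54.1% to 71.8%.

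In amino acid transport 21 of 35 genes were higher in young hearts and 3 lower (22 and 4 adjusted over the list alone), median 1.17 (camera adjusted p = 0.0148, and adjusted p = 0.385 with an estimated correlation). slc1a5 rose by 3.61 (SE 0.22), slc7a5, the large neutral amino acid exchanger LAT1, by 5.60 (SE 0.40) and slc38a2 by 1.19 (SE 0.27). Amino acid metabolism had 28 of 46 higher and 12 lower, the same adjusted over the list alone, median 1.44 (camera adjusted p = 0.0248, and adjusted p = 0.270 with an estimated correlation), a call lost under library totals (camera adjusted p = 0.0586). mthfd1l, of mitochondrial one-carbon metabolism, rose by 7.48 (SE 0.56) and gfpt2 by 6.60 (SE 0.44). Of 50 mTOR pathway genes 10 rose and 19 fell, median -0.39, but 0.21 under library totals (camera adjusted p = 0.0714). The list passed without control replicate 1 (camera adjusted p = 0.0300) and without either 3 dpi library (camera adjusted p = 0.0460 and 0.0487), and with fry (adjusted p = 0.0345). eif4e1c rose by 3.30 (SE 0.22) and sesn2, a sestrin gene of leucine sensing, by 3.49 (SE 0.25), whereas tsc1a, of the complex that restrains mTOR, changed by -2.75 (SE 0.31). Aminoacyl-tRNA synthetases had 18 of 21 higher and 1 lower, the same adjusted over the list alone, median 1.67 (camera adjusted p = 9.44e-05, and adjusted p = 0.387 with an estimated correlation), with yars at 3.203 (SE 0.22). Ribosome biogenesis had 25 of 47 higher and 4 lower, median 0.91 (camera adjusted p = 0.00736, and adjusted p = 0.580 with an estimated correlation). Integrated stress genes had 14 of 24 higher and 1 lower, median 0.87 (camera adjusted p = 0.0121, and adjusted p = 0.385 with an estimated correlation), with asns at 3.26 (SE 0.27).

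Cell cycle genes were higher in young hearts in 42 of 53 cases and lower in 0 (43 and 0 adjusted over the list alone), median 2.4997 (camera adjusted p = 4.19e-06, and adjusted p = 0.510 with an estimated correlation), with pcna at 2.86 (SE 0.30) and ccnb1, cyclin B1, at 4.33 (SE 0.52). Sarcomere genes were lower in 29 of 37 cases and higher in 5, the same adjusted over the list alone, median -2.66 (camera adjusted p = 8.52e-06, and adjusted p = 0.387 with an estimated correlation). tnnt2a, cardiac troponin T, changed by -5.69 (SE 0.50) and desma, desmin, by -3.46 (SE 0.30). vmhc was higher by 0.94 (SE 0.32, edgeR adjusted p = 0.0255), a call lost without any 1 of the control, 7 dpi or young libraries (adjusted p from 0.0510 to 0.138). Oxidative phosphorylation had 48 of 88 genes lower and 3 higher (47 and 3 adjusted over the list alone), median -0.88, or -0.24 under library totals (camera adjusted p = 1.88e-06, and adjusted p = 0.580 with an estimated correlation). cox5b2 changed by -7.69 (SE 0.47) and cox6a1 rose by 3.33 (SE 0.27). Fatty acid oxidation had 29 of 35 lower and 2 higher, median -1.56 (camera adjusted p = 2.62e-06, and adjusted p = 0.385 with an estimated correlation), with cpt1b, of mitochondrial fatty acid import, at -3.50 (SE 0.25). Glycolysis had 21 of 39 lower and 8 higher, median -0.99, or -0.38 under library totals with 15 lower and 13 higher (camera adjusted p = 0.0148, and adjusted p = 0.331 with an estimated correlation). Ribosomal protein genes had 36 of 82 lower and 4 higher (34 and 3 adjusted over the list alone), median -0.64, or -0.01 under library totals with 28 lower and 24 higher (camera adjusted p = 0.000103, and adjusted p = 0.594 with an estimated correlation). Ribosomal proteins and oxidative phosphorylation did not pass with fry (adjusted p = 0.0635 and 0.0506). Genes of small proteins had a median of 0.51 and those of giant proteins -0.21.

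Wnt targets and injury genes were also higher in young hearts. Of 22 Wnt targets 15 rose and 3 fell (15 and 4 adjusted over the list alone), median 2.40 (camera adjusted p = 0.00384, and adjusted p = 0.331 with an estimated correlation). wif1 and dkk1b, secreted Wnt inhibitors, rose by 3.88 (SE 0.29) and 5.45 (SE 0.42). In the injury list 26 of 44 rose and 12 fell (27 and 13 adjusted over the list alone), median 1.71 (camera adjusted p = 0.0265, and adjusted p = 0.387 with an estimated correlation), a call lost under library totals (camera adjusted p = 0.0826). il11b rose by 6.99 (SE 0.46) and mmp9 by 6.11 (SE 0.41).

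Blood and most immune cell markers differed between young and adult hearts. Macrophage markers had 24 of 32 lower and 3 higher (25 and 4 adjusted over the list alone), median -4.51 (camera adjusted p = 2.66e-07, and adjusted p = 0.385 with an estimated correlation), with the antigen presentation genes cd74a and cd74b at -11.61 (SE 0.50) and -10.13 (SE 0.38). Lymphocyte markers had 16 of 23 lower and 2 higher, median -3.98 (camera adjusted p = 5.86e-05, and adjusted p = 0.160 with an estimated correlation). Neutrophil markers did not pass (7 of 25 higher, 11 lower, median -0.72, camera adjusted p = 0.234). Adult erythroid genes had 16 of 22 lower and 1 higher, median -5.38 (camera adjusted p = 1.88e-06, and adjusted p = 0.185 with an estimated correlation). The adult globin gene hbaa1 was at 0 in both young libraries and at least 52030-fold lower than in control, at a floor of 3 counts over the group. gata1a, an erythroid transcription factor gene, changed by -6.63 (SE 0.28). Embryonic erythroid genes had 8 of 10 higher and 2 lower, median 6.93, or 3.81 with unseen genes at their bound (camera adjusted p = 0.00384, and adjusted p = 0.331 with an estimated correlation). hbae3 stood at 266 and 185 CPM in young hearts and at 0.246 and 0 CPM in control. Endothelial and endocardial markers had 23 of 35 lower and 5 higher, median -1.39 (camera adjusted p = 4.06e-05, and adjusted p = 0.160 with an estimated correlation), with klf2a, a flow-responsive transcription factor gene, at -4.16 (SE 0.23) and vwf at -4.43 (SE 0.32). Smooth muscle and bulbus genes did not pass as a list (10 of 20 higher, 4 lower; median 1.49, with camera adjusted p = 0.211, and fry adjusted p = 0.00820), while elnb, an elastin gene, rose by 6.86 (SE 0.70). Skeletal muscle genes had 25 of 31 higher and 4 lower, median 5.27 (camera adjusted p = 7.43e-06, and adjusted p = 0.331 with an estimated correlation), with atp2a1 at 6.96 (SE 0.49). Markers of other organs had 30 of 42 higher and 3 lower (31 and 3 adjusted over the list alone), median 5.70, or 4.42 with unseen genes at their bound (camera adjusted p = 7.43e-06, and adjusted p = 0.217 with an estimated correlation). The lens gene crygn2 rose by 10.06 (SE 0.53). apoa2, an apolipoprotein gene of the liver, and tm4sf4 were at 0 in both control libraries and at least 565-fold and 4354-fold higher in young hearts.

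Changes at 3 dpi and in young hearts, both against control, overlapped. Of the genes called in both, 2007 changed in the same direction, 1032 up and 975 down, and 407 in opposite directions; independent calls would give 920 and 896. All 14 aminoacyl-tRNA synthetases that rose at 3 dpi also rose in young hearts, 43 oxidative phosphorylation genes and 22 fatty acid oxidation genes fell in both, and 10 cell cycle genes rose in both. In contrast 19 macrophage markers rose at 3 dpi and were lower in young hearts. Sarcomere medians were negative in both, at -0.86 for 3 dpi and -2.66 for young hearts. Whether a lower share of cardiomyocyte RNA gives the shared falls was not tested, nor whether RNA of other larval organs adds to the shared rises. Run and group cannot be told apart for young hearts. The comparisons share their 2 control libraries. In 20 simulations without change, sharing gave a covariance of log2 fold changes of 0.12, against 1.18 in the data. The data gave 1.99 without control replicate 1 and 1.81 without control replicate 2, settings that were not simulated. All simulated libraries were drawn from the control mean with a spread pooled over groups. They do not reproduce how far the control libraries differ in the data, so 0.12 does not bound the part that sharing gives. The simulations gave at most 1 gene called in the same direction, which follows from having no changed genes. That count therefore does not show how far shared controls raise the overlap. The numbers from independent calls leave the shared controls out too. The correlation was 0.31, below the 0.53 of the simulations, whose fold changes hold noise alone. Without control replicate 2 the count in the same direction was 734 and without 3 dpi replicate 1 it was 706.

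Changes at 3 and 7 dpi against control showed no excess of the same direction over the opposite. Of the genes called in both, 647 changed in the same direction, 445 up and 202 down, and 758 in opposite directions, where independent calls would give 581 and 587. The covariance was 0.05, below the 0.12 of the simulations. It was 0.24 with DESeq2, 0.26 without control replicate 1 and 0.80 without control replicate 2, and from 0.05 to 0.12 in the other settings tried. Those settings were not simulated. In oxidative phosphorylation 58 genes fell at 3 dpi and rose at 7 dpi, and 12 genes of fatty acid oxidation did so, while 11 smooth muscle genes and 9 aminoacyl-tRNA synthetases rose at both times. The counts moved with single libraries, and their balance with either control library and with 3 dpi replicate 1, but not with a young library: the same and opposite counts were 243 and 552 without control replicate 1, 351 and 162 without control replicate 2, 277 and 241 without 3 dpi replicate 1, and 426 and 521 or 423 and 502 without either young library.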

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

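The tests against a lower share of cardiomyocyte RNA and against a few genes taking most of the counts were chosen only after the result was seen, and the lists of giant and small proteins were written after the rise at 7 dpi had been seen. The results in this part, apart from macrophage markers, which are weighed here as a pattern, were singled out because the change against control passed in opposite directions at 3 and 7 dpi and the difference between these times passed as well. The difference is tested as 7 dpi against 3 dpi with 2 libraries per group, and the 7 dpi libraries carry a run prefix that no other group shares, so run and time cannot be told apart for any of them.

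Genes that rose at 3 dpi and fell at 7 dpi were mmp9 (2.84 and -1.80, a difference of -4.64 on the log2 scale), anln (2.30 and -1.99, difference -4.29), csf1ra (2.14 and -3.65, difference -5.79), xirp1 (1.68 and -1.82, difference -3.50) and spi1b (2.40 and -1.54, difference -3.94). Genes that fell at 3 dpi and rose at 7 dpi included those of respiration and fatty acid use: cox7a1 (-2.66 and 2.04, difference 4.70), ndufs5 (-1.12 and 3.64, difference 4.76), cox5b2 (-1.57 and 2.66, difference 4.22), fabp3 (-2.16 and 1.81, difference 3.97), decr1 (-2.30 and 1.31, difference 3.61) and cpt1b (-1.56 and 0.78, difference 2.34). Genes of mTOR signalling and translation control did so too, namely akt1s1 (-1.32 and 0.98, difference 2.30), eif4ebp1 (-1.10 and 1.04, difference 2.13) and eif4ebp3 (-1.66 and 2.13, difference 3.78). The others were chac1 (-1.35 and 1.75, difference 3.10), gata1a (-1.23 and 0.74, difference 1.97), klf2a (-1.26 and 0.55, difference 1.82) and nr1d1 (-1.27 and 0.79, difference 2.06). Among lists, the medians were -0.53 and 2.17 for ribosomal proteins (difference 2.64), -1.15 and 1.81 for oxidative phosphorylation (difference 2.97), -0.58 and 0.72 for glycolysis (difference 0.94) and 1.14 and -1.80 for neutrophils (difference -3.27). With an estimated correlation 0 of these lists passed in any of the comparisons, and with fry the 3 dpi changes of ribosomal proteins (adjusted p = 0.231), oxidative phosphorylation (0.0650) and neutrophils (0.0912) did not pass. The ribosomal protein change at 3 dpi was also lost without control replicate 2 (camera adjusted p = 0.102). Library totals lower every log2 fold change between 3 and 7 dpi by about the shift of the median, -1.69, which takes glycolysis to -0.77, and end its call at 7 dpi against control (camera adjusted p = 0.395). Opposite calls at both times held under library totals for mmp9, anln, csf1ra, xirp1, spi1b, eif4ebp3 and cox5b2. The rise at 7 dpi did not pass there for cox7a1 (0.81), fabp3 (0.58), chac1 (0.51) and decr1 (0.07), and turned negative for akt1s1 (-0.25), eif4ebp1 (-0.20), cpt1b (-0.48), gata1a (-0.505), nr1d1 (-0.48) and klf2a (-0.71, a call). The difference between the times did not pass there for eif4ebp1 (0.44), gata1a (0.28), klf2a (0.12) and nr1d1 (0.37), and the rise of klf2a at 7 dpi did not pass with upper-quartile scaling (edgeR adjusted p = 0.119). The fall of ndufs5 at 3 dpi did not pass under library totals (-0.67). With limma on log2 RPM the calls at 3 dpi of akt1s1, ndufs5, chac1, eif4ebp1, eif4ebp3, gata1a, klf2a and nr1d1 were lost. At 7 dpi the same setting lost the rises of eif4ebp3 (0.93, limma adjusted p = 0.0532), cox7a1, fabp3, decr1, cpt1b, chac1, akt1s1, eif4ebp1, gata1a and nr1d1. It called klf2a lower there (-0.70). The difference between the times was lost for akt1s1, eif4ebp1, gata1a, klf2a and nr1d1. Without control replicate 2 the rise of xirp1 at 3 dpi did not pass (edgeR adjusted p = 0.0532).

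Ribosomal protein and oxidative phosphorylation genes rose at 7 dpi with medians of 2.17 and 1.81. If a few genes took most of the counts, other genes could only lose share under library totals. There the ribosomal protein median was 0.93 with a lower quartile of 0.42, so most of these genes did not lose share. Their part of all counts was 5.66% and 7.74% in control and 12.9% and 11.2% at 7 dpi. Ribosomal protein genes may thus be among those that gained the counts, and the test cannot decide for them. The oxidative phosphorylation median of 0.57 with a lower quartile of -0.01 leaves it open for that list. This split by list was made after the values were seen. Recovery that depends on transcript size may account for much of the rise: genes of small proteins exceeded genes of giant proteins by 2.69 in median log2 fold change, most ribosomal and respiratory proteins are small, and the control replicates differ from each other by 1.15 in the same measure. Another sequencing run cannot be told apart from time, because 0 other groups share the run prefix of the 7 dpi libraries. A biological rise of these genes at 7 dpi stays open, as untested.

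Macrophage markers rose at 3 dpi with a median of 1.71 and quartiles of 1.31 and 2.34. A lower share of cardiomyocyte RNA alone would raise markers of other cell types alike. The medians of lymphocytes, -0.63, and endothelium, -0.15, argue against that, with upper quartiles of -0.0038 and 0.446, below the lower quartile of macrophages. Adult erythroid genes had a median of -0.98. Other lists did rise, with medians of 1.63 for smooth muscle and bulbus, 1.14 for neutrophils and 0.43 for epicardium and fibroblasts. A lower share that contributes to the rises is not excluded. Recovery by size is argued against by a difference between the lists of small and giant proteins of -0.09. More macrophages in the heart, or more transcripts per macrophage, may each underlie the rise, and these libraries cannot separate them.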

How the results depend on the processing

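Scaling by library totals, the fit without the 7 dpi libraries and whole reads recovered from the RPM table were chosen only after the data were seen; the other alternatives were planned. Of 150 single-gene results recomputed, 130 kept their direction and their side of the threshold under every alternative run. With a correlation estimated from the data, 0 lists passed in each of the 4 comparisons, against 15, 10, 11 and 20 of 26 with the preset correlation. The estimate rests on 4 residual degrees of freedom. A correlation above the preset 0.01 does not account for every lost call. In young hearts the estimates were -0.0106 for endothelial, 0.00752 for lymphocyte and 0.00177 for amino acid metabolism lists. Their camera adjusted p still went from 4.06e-05, 5.86e-05 and 0.0248 to 0.160, 0.160 and 0.270. With an estimated correlation camera also takes its p-value from the 4 residual degrees of freedom, whereas the preset one gives it far more. This alone raises the p-values. How much of each lost call comes from it was not separated.

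Genes called at 3 dpi against control were 3015, and 1823 with only the 2 groups compared. There fewer libraries estimate the spread, and 16129 genes were tested in place of 19330. These changes were not separated. Leaving out each library in turn gave 985 to 3287. Genes called at 7 dpi against control were 7486, and 11770 with library totals, which lower nearly all fold changes at 7 dpi. Leaving out each library gave 4093 to 7750. With the replicate number as a block (replicate block) the counts were 2650, 6854, 9183 and 10989 for 3 dpi, 7 dpi, 7 against 3 dpi and young. Differences between replicates correlated between groups by -0.14 to 0.0679, so the numbers carry little pairing. Whole reads recovered from the RPM table gave 2195, 6128 and 8258 in the adult comparisons, and limma on log2 RPM 3254, 9720 and 11736.

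The overlap of 3 dpi and young changes in the same direction was 2007 genes, and 706 to 2186 with each library left out. That of 3 and 7 dpi changes was 647, 243 to 746 with each library left out, and 398 with an absolute log2 fold change of at least 1. A library left out of a group of 2 leaves 1, which the fit assumes to vary like the rest.

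The fold change of vmhc between 3 and 7 dpi, -0.03 and far from the threshold, changed sign with RLE scaling (0.005), only the 2 groups compared (0.008), adult libraries only (0.023), the replicate block (0.013) and whole reads recovered from the RPM table (0.01). Leaving out each library gave -0.435 to 0.506. It was a call with library totals (-1.73, edgeR adjusted p = 0.00118) and with limma on log2 RPM (-1.65, adjusted p = 0.00469). Ribosome biogenesis between 3 and 7 dpi, with a test direction of up and a camera adjusted p of 0.793, turned to down with library totals (camera adjusted p = 0.00816). The cause of the sign changes of vmhc near 0 was not tested. Library totals themselves move the median of all genes by -1.69, which accounts for most of the change of vmhc, from -0.03 to -1.73. Camera compares the members of a list with the other genes. A shift common to all genes therefore does not account for the change of the ribosome biogenesis list, whose cause was not tested. RPM values are scaled to the same totals.

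On simulated data with 200 scored changes among 19330 genes, between 9% and 11% of genes changed 2-fold were called. Of genes changed 4-fold between 74% and 82% were called. The shares in the data, where far more genes passed, were not measured.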

Other observations

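The lists of this part were written, and the count of other organ markers was chosen, only after the data were seen.

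Proteasome genes were higher at 3 dpi than in control: 28 of 43 rose and 0 fell, median 0.98 (camera adjusted p = 1.23e-12, and adjusted p = 0.624 with an estimated correlation), with psma2 at 1.25 (SE 0.22) and psmd14 at 1.23 (SE 0.22). In the interferon list 8 of 34 rose and 0 fell, median 0.86 (camera adjusted p = 0.000866, and adjusted p = 0.624 with an estimated correlation), with mxa at 2.91 (SE 0.43) and gbp1 at 2.44 (SE 0.42). Of 35 circadian clock genes 13 fell and 1 rose, median -0.75, or -0.32 under library totals (camera adjusted p = 3.74e-06, and adjusted p = 0.380 with an estimated correlation), with the clock genes nr1d1 at -1.27 (SE 0.22) and tefa at -1.57 (SE 0.26). The fall of nr1d1 did not pass with limma on log2 RPM (adjusted p = 0.0806). At 7 dpi 11 fell and 3 rose, median -0.44, or -1.68 under library totals (camera adjusted p = 0.0355, and adjusted p = 0.380 with an estimated correlation). The time of day of collection is not given in the sources used here. Hypoxia genes (6 of 31 higher, 6 lower, median 0.13) and cardiac ion channels (2 of 29 higher, 4 lower, median 0.09) did not pass (camera adjusted p = 0.889 for each). Mitochondrial ribosome genes had a median of -0.39, but 0.07 under library totals, with 0 of 73 higher and 4 lower (camera adjusted p = 8.07e-05, and adjusted p = 0.970 with an estimated correlation). At 7 dpi 70 of 73 rose and 0 fell, median 1.81, or 0.57 under library totals (camera adjusted p = 1.50e-23, and adjusted p = 0.380 with an estimated correlation), and 39 of 43 proteasome genes rose and 0 fell, median 1.23, but -0.02 under library totals (camera adjusted p = 9.31e-15, and adjusted p = 0.380 with an estimated correlation).

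In young hearts 23 of 25 cholesterol synthesis genes were higher than in control and 1 lower, median 3.43 (camera adjusted p = 1.50e-07, and adjusted p = 0.123 with an estimated correlation), with cyp51 at 5.37 (SE 0.31) and lss at 4.81 (SE 0.32). Interferon genes were lower in 23 of 34 cases and higher in 5, median -2.44 (camera adjusted p = 1.58e-05, and adjusted p = 0.380 with an estimated correlation), with stat2 at -2.998 (SE 0.22) and gbp1 at -2.82 (SE 0.45). Circadian clock genes were lower in 23 of 35 cases and higher in 3, median -2.51 (camera adjusted p = 6.40e-06, and adjusted p = 0.202 with an estimated correlation), with per1b at -7.03 (SE 0.34) and tefa at -5.63 (SE 0.31).

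Markers of lens, skeletal muscle, liver and other organs were higher in the young libraries, with a median of 5.70 for the list of other organs, or 4.42 with unseen genes at their bound. Of the 42 tested members 33, or 78.57%, had a log2 fold change above 1, and the lens gene crygn2 stood at 254 and 125 CPM. Recovery by size is argued against as the whole cause, since the lists of small and giant proteins differed by 0.72, less than the bound of the organ list. The limits written for that test left 0.72 open, and the comparison with the organ list was added after the value was seen. RNA of other larval organs in the heart pools and expression of these genes by larval heart cells both stay open, since either would give such a share.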
